A study of Mus musculus with 24 samples.

How the data were processed

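The samples were HBC-3 cells, a mouse hepatoblast line that can take on hepatocyte or bile duct features, grown on Matrigel, a gel of basement membrane proteins. RNA was taken at day 0 and at each of days 1 to 7, with 3 arrays per day lettered A, B and C, which gives 24 arrays in 8 groups. Per the labels' protocols, the cells were freed of their STO fibroblast feeder layer by trypsin treatment and replating, total RNA was amplified, and labelled targets were made with random primers. Each array carried a Cy3 target from undifferentiated HBC-3 cells as the common reference and a Cy5 target from the sample, per the labels' protocols. On the day 0 arrays both channels therefore held undifferentiated cells. Dyes were not swapped in any label.

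The authors deposited a table of log ratios with 24157 features and 24 columns, taken here as log2 of Cy5 over Cy3. The base and the numerator of the ratio are not given in the sources used here. The range of the values makes base 2 likely, and the dyes in the labels make the sample the likely numerator. The scanner, the background correction, the normalization and the reason for empty cells are likewise not given in the sources used here, so scale, centring and direction stay unknown beyond this reading. Column medians as deposited lay between -0.025 and 0.029. They were 0.0118, -0.0052 and 0.0005 for day 0 arrays A, B and C, 0.010, 0.0094 and 0.005 for day 1, and 0.0027, -0.0025 and -0.0022 for day 2. For day 3 they were -0.0034, 0.0083 and 0.0027, for day 4 0.0073, -0.0086 and 0.0065, and for day 5 -0.0044, -0.0121 and 0.0171. For day 6 they were 0.0295, 0.0151 and 0.0094, and for day 7 0.0137, -0.0253 and 0.0075.

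Gene symbols came from the annotation of the array platform, which listed 13908 features. Of these, 13319 had 1 symbol and 589 had several genes and were left unnamed, as were the 10249 features the annotation did not list. Symbols were brought up to date through Entrez identifiers in a table of mouse genes of assembly GRCm38.p6, used for names only. This matched 13290 features, and 29 kept their annotated symbol, which gave 8315 different symbols. The unit tested was a gene, as the mean per array over its features, or an unnamed feature. Of 19153 units with any value, 10639 had values on at least 2 arrays in each of the 8 groups and were tested, 5660 of them genes and 4979 unnamed features. Of the genes, 2870 had more than 1 feature.

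Each array was centred on its median. Means of the 8 days were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. Tests were 2-sided. Nothing in the labels says whether the arrays of a day came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays, 3 per day, limits the precision, and the median standard error of a change against day 0 was 0.311 to 0.317 (log2). Comparisons, lists and rules were fixed before the data were examined. Comparisons were each day against day 0, any change over the course (moderated F-test), days 5 to 7 against days 1 to 3, and each day against the day before. The difference between the day 7 and day 1 effects was tested in the same fit.

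The genes named were fixed by rule for day 1 against day 0, day 7 against day 0, and days 5 to 7 against days 1 to 3. They were the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, with a value on every array compared and no overlap between the sides. To these were added up to 4 members past the threshold from each of 26 fixed gene lists, by size of change, and 16 fixed genes of liver and signalling biology at days 1 and 7 whatever their p. Some genes that the rule takes from lists are given in the text as part of a count only. Genes outside the rule are named in the text as chosen after their values were seen.

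Gene lists were tested with limma's cameraPR on the moderated t at a preset correlation of 0.01, for lists with at least 4 measured members. The test was repeated with a correlation estimated from residuals (statmod 1.5.0 and limma), and with limma's fry. Adjustment was over the lists of a comparison. Calls were counted after adjustment over all units and adjusted over the list alone. With the estimated correlation, 1 list kept a rise and 1 a fall at day 1, likewise at day 7, and 0 lists were called between late and early days.

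Before use, the fit was tested on simulated data for day 7 against day 0 with 10639 units, 200 of them changed. It recovered 26% of units changed by 1 (log2) and 79% of those changed by 2, with the right sign in 100% of calls of changed units. It made 10 false calls, 8.7% of its calls.

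Replicate letters were checked for pairing by the correlation of deviations from the day mean. Same-letter arrays correlated at 0.193 to 0.413 within days 1 to 3 and at 0.161 to 0.932 within days 4 to 7, so letters were read as pairs within each of these periods. Day 0 with later days gave -0.542 to 0.454, days 1 to 3 with days 5 to 7 -0.288 to 0.292, and day 3 with day 4 0.012 to 0.151, so letters were not read as pairs between periods. No array pair of 276 shared over 1% identical values (0 pairs).

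Alternatives fixed beforehand were no centring, scaling to a common median absolute deviation, quantile normalization, a stricter and no filter on missing values, robust eBayes, features in place of genes, a fit on the compared groups only, days against the reference channel in place of day 0, a minimum change of 1 (log2), the replicate letter as a block, and leaving out each array and each letter. Chosen after seeing the data were leaving out the C arrays of days 4 to 7, turning the sign of day 0 array C or of all day 0 arrays, and the letter within a period as a random or fixed block. Figures were drawn from these results.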

Results

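Transcript levels were measured in HBC-3 mouse hepatoblasts on 24 arrays of 2 colours, 3 for day 0 and 3 for each of days 1 to 7 on Matrigel. The labels describe the series as differentiation induced by Matrigel, and the comparisons ask which transcripts changed from the undifferentiated state and when. Values per array ranged from 12328 to 22149 of 24157 features. The SD of the log ratios ranged from 0.332 on day 0 array C to 1.064 on day 7 array C. Values are log2 of sample over reference, a reading that is likely but not stated with the deposited table, and errors are standard errors of the fit unless given as SD.

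The arrays of days 1 to 7 resembled each other, with a mean correlation across features of 0.668 over 210 pairs (range 0.388 to 0.967). Features are not independent replicates, so these values describe the arrays only. Within days 1 to 3, arrays A and C of a day correlated at 0.889 to 0.921 and array B with either at 0.750 to 0.840. Within days 4 to 7, the C arrays correlated with each other across days at 0.808 to 0.967, but with the A and B arrays of their own day at only 0.468 to 0.624. At day 0, where both channels held undifferentiated cells, arrays A and B correlated at 0.755, A and C at -0.343, and B and C at 0.084. Day 0 array A and day 3 array B correlated at -0.504. Correlations this far below 0 between arrays of the same dye orientation do not show a turned sign. Those among the day 0 arrays would be the same with all of them turned. Since the direction of the deposited ratios is not stated, turned signs serve as a check only. Counts, lists called and the overlap of day 1 and day 7 are given with the sign of the day 0 arrays turned too. For named genes the text gives how many calls stayed.

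**Figure D1:**
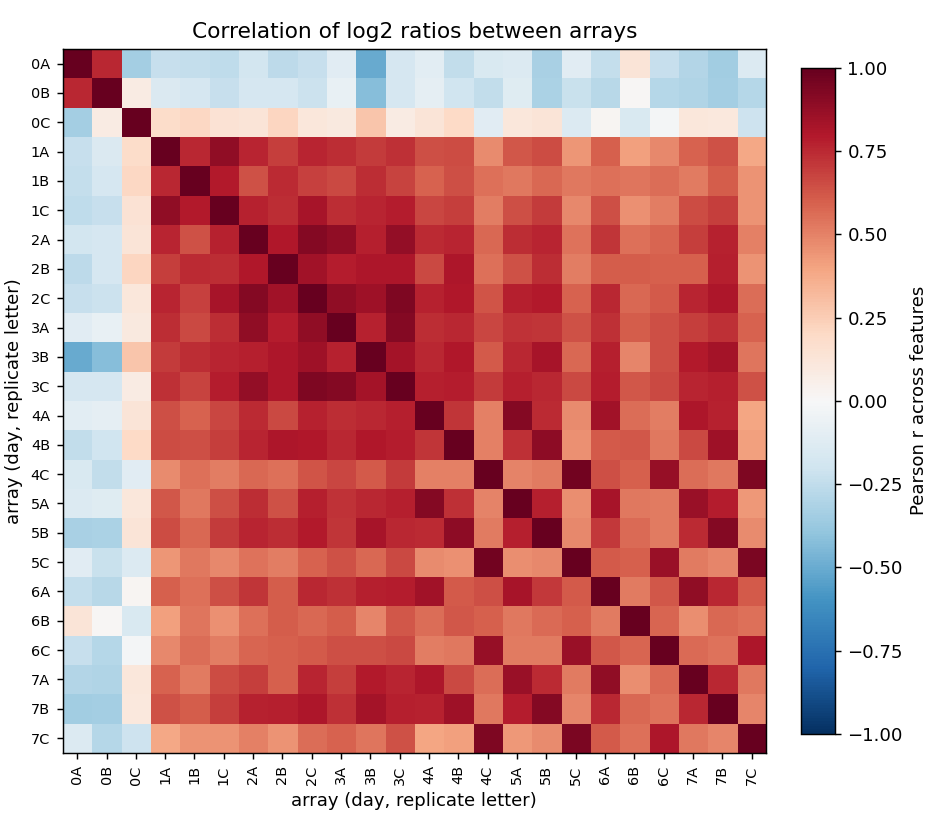
Pearson correlation of log2 ratios across features for each pair of the 24 arrays, labelled by day and replicate letter. Colour runs from -1 (blue) to 1 (red); day 0 arrays A and C stand at -0.343, and the C arrays of days 4 to 7 correlate with each other at 0.808 to 0.967.

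Changes against day 0 were present by day 1. Past the threshold were 1161 units at day 1 (531 higher, 630 lower), 1818 at day 2 (963 and 855), 2599 at day 3 (1294 and 1305) and 2359 at day 4 (1201 and 1158). At days 5, 6 and 7 they were 2435 (1243 and 1192), 2642 (1300 and 1342) and 2940 (1552 and 1388). The F-test over the whole course called 1738 units, 934 of them genes. With the sign of all day 0 arrays turned, the counts were 515, 1109, 1366, 1499, 1342, 1776 and 1230 for days 1 to 7 and 1085 for the whole course. Whether later days gave more calls than day 1 depended on the processing. With arrays scaled, 3259 units passed at day 1 and 2694, 2797 and 2712 at days 4, 5 and 6, and with only the compared groups fitted 2577 at day 1 and 1212, 1117, 1449 and 1607 at days 4 to 7. With only array C of day 0 turned, the counts were 1705, 2411, 3003, 2757, 2719, 2767 and 3206, and 2091. Without the C arrays of days 4 to 7, the F-test called 3166 units. It called 894 without day 0 array A and 753 without day 0 array B.

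**Figure D2:**
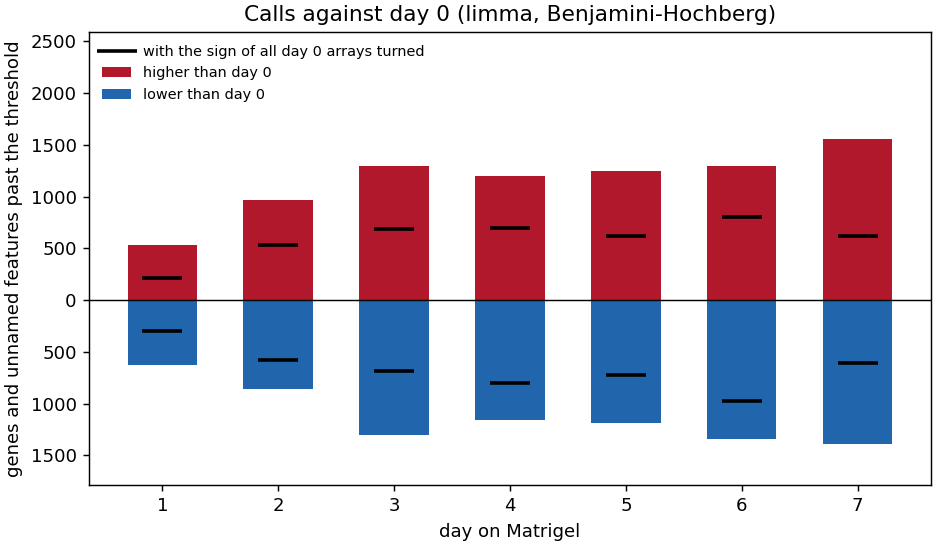
Genes and unnamed features past the threshold against day 0 on each day on Matrigel, those higher drawn above 0 and those lower below it, from 531 and 630 at day 1 to 1552 and 1388 at day 7. Black marks give the counts with the sign of all day 0 arrays turned, 215 and 300 at day 1 and 619 and 611 at day 7.

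The largest changes after 1 day on Matrigel, among genes with a value on every array compared, were these. Tgfbi, which encodes a matrix protein induced by TGF-beta, rose by 3.37 ± 0.49 (adjusted p = 0.00056, limma, n = 3 arrays per day). Fzd1, a Wnt receptor, rose by 3.15 ± 0.65, and Clu, the secreted chaperone clusterin, by 3.01 ± 0.54. Olfml3, Ndrg2, Pxylp1, Bnip3 and Abhd4 rose by 2.54 to 2.83. Cemip, which encodes a protein of hyaluronan breakdown, fell by 4.19 ± 0.44 (adjusted p = 1.25e-05), and Vat1l, Upk1b and Prss23 fell by 3.83, 3.75 and 3.49. Zyx, which encodes the focal adhesion protein zyxin, fell by 3.41 ± 0.70, Aldh1a1, a retinaldehyde dehydrogenase, by 3.38 ± 0.35, Aif1l by 3.28 and the integrin subunit Itga3 by 3.25. Of these, Fzd1, Clu, Olfml3, Pxylp1, Bnip3, Zyx and Itga3 no longer passed with the sign of all day 0 arrays turned, and the order changed: Ndrg2 (2.31) then lay above Tgfbi (2.14), and Prss23 and Upk1b (-3.91 and -3.86) below Cemip (-2.56).

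Among the fixed lists, lysosomal transcripts rose together at day 1. Of 22 measured members 8 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.99 and an adjusted p of 1.41e-07 (limma cameraPR), or adjusted p = 0.0614 with an estimated correlation. Ctsb, Ctsa and Hexa, all lysosomal enzymes, rose by 1.71, 1.42 and 1.34. Of 12 matrix proteases and inhibitors 5 rose and 0 fell (6 and 1 over the list alone; median 1.01, adjusted p = 0.00756, and adjusted p = 0.0371 with an estimated correlation), among them Adam12 by 2.37 ± 0.38 and Plat, tissue plasminogen activator, by 2.17 ± 0.59. Of 14 transcripts of epithelial junctions and polarity 3 fell and 0 rose (5 and 0 over the list alone; median -0.63, adjusted p = 0.0086, and adjusted p = 0.0208 with an estimated correlation). These were the tight junction protein gene Cgn by -2.65 ± 0.44, the gap junction gene Gja1 by -1.37 and Prkci by -1.07. Of 39 transcripts of DNA replication and the cell cycle 3 fell, Cks2, Cdc6 and Cks1b, and 0 rose (the same counts adjusted over the list alone; median -0.37, adjusted p = 0.0086, and adjusted p = 0.144 with an estimated correlation). Of 12 transcripts of cholesterol and fatty acid synthesis 3 fell, Idi1 by -1.99, Msmo1 by -1.43 and Sqle by -1.40, and 0 rose (3 and 0 over the list alone; adjusted p = 0.0106, and adjusted p = 0.148 with an estimated correlation). Of 16 transcripts of glycolysis and the hypoxia response 3 rose and 0 fell (3 and 0 over the list alone; adjusted p = 0.0384, and adjusted p = 0.196 with an estimated correlation). These were Bnip3 and Bnip3l, whose proteins act in the removal of mitochondria, and the oxygen-regulated factor gene Hif1a, by 2.55, 1.75 and 1.61, and none is a glycolytic enzyme.

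Markers of fibroblasts, the cell type of the feeder layer, stood higher at day 1 as well. Of 10 measured, 3 rose and 0 fell (6 and 0 over the list alone; median 1.12, adjusted p = 0.000377, and adjusted p = 0.138 with an estimated correlation), with Pdgfrb, Col6a1 and Col5a1 at 2.29, 1.81 and 1.43. On the same arrays, day 0 arrays A and B lay below day 0 array C by a median of -0.65 over the lysosomal list and -0.91 over the fibroblast list. With the sign of all day 0 arrays turned, the list medians at day 1 were 0.26 for lysosome, -0.41 for cholesterol synthesis, 0.47 for matrix proteases, -0.90 for junctions, -0.30 for the cell cycle and 0.02 for fibroblast markers. The calls of matrix proteases, fibroblast markers and glycolysis were then lost, and that of glycolysis also without day 1 array B (median 0.23) or with array C of day 0 turned (0.62).

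Other lists did not pass as sets at day 1 by cameraPR, though fry called some of them, as given below. Of the fixed members only 4 of 37 hepatocyte, 4 of 26 ductal and 11 of 34 Notch pathway transcripts were measured. That is too few to judge hepatocyte or duct differentiation. Of 16 integrin and focal adhesion transcripts 3 rose and 7 fell (3 and 8 over the list alone; median -0.52, adjusted p = 0.062), with Itgb3 at 3.75 ± 0.49 and Actn1 at -2.38 ± 0.73. Of 24 transcripts of the TGF-beta and BMP pathway 5 rose and 2 fell (6 and 2 over the list alone; adjusted p = 0.0738). Of 14 Wnt pathway transcripts 3 rose and 0 fell (3 and 0 over the list alone; adjusted p = 0.356), with a median of -0.03 but a mean of 0.27. Of 9 transcripts of growth arrest 1 rose, Btg1 by 1.76 ± 0.27, and 1 fell, Gadd45g by -3.18 ± 0.37. Of 14 detoxification transcripts 2 rose, the metallothionein genes Mt1 and Mt2 by 2.09 and 2.07, and 2 fell, Aldh1a1 and the transporter gene Abcc3; here the median was 0.23 and the test leaned downward (adjusted p = 0.898). Of 6 inflammation transcripts Socs3 and Stat3 rose by 2.01 and 1.12. Of 12 interferon response transcripts Usp18 and Gbp2 fell by -1.89 and -1.70. Of 20 cytoskeletal transcripts 1 rose and 1 fell, of 33 of oxidative phosphorylation 0 rose and 1 fell, and of 4 ductal markers Itga6 rose by 0.86. None passed among 47 ribosomal proteins, 22 of the unfolded protein response, 11 of the Notch pathway, 10 of the extracellular matrix, 6 immediate early, 4 hepatocyte and 2 endothelial transcripts (0 each). Of 3 blood cell markers the globin gene Hba-a1 rose by 1.33 ± 0.35, with 1 of its 7 features opposite in sign, and of 2 smooth muscle markers Smtn fell by -1.03. Among the genes fixed whatever their p, Bmp4 fell by -2.13 ± 0.51 (adjusted p = 0.0126), while Afp, Id2 and Id3 stood at 0.47, -0.90 and -0.40 (adjusted p = 0.743, 0.381 and 0.54). Krt19 had values on 14 arrays and Jag1 on 1 array, too few to test. The other 10 had no feature listed under their symbol and were not analysed here.

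At day 1, 59 named genes passed the threshold. With the sign of all day 0 arrays turned, 30 stayed past it in the same direction, 27 no longer passed and 2 changed sign. Against the reference channel, with no day 0 array in the contrast, 54 of the 59 stayed and 5 no longer passed. The day 0 arrays still enter the shared estimate of spread, and a dye bias is then not removed. The count of 1161 fell to 405 without day 0 array A, 330 without day 0 array B, and 541, 623 and 459 without day 1 array A, B and C. It was 2271 without the C arrays of days 4 to 7.

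The largest changes after 7 days, among genes with a value on every array compared, were these. Clu rose by 6.68 ± 0.54 (adjusted p = 1.58e-07, limma, n = 3 arrays per day), Dcn, the matrix proteoglycan decorin, by 6.06 ± 0.69, and Selenop, the plasma selenium carrier made by liver, by 5.27 ± 0.47. Nrep rose by 4.89, Lbp, the lipopolysaccharide-binding protein of the acute phase, by 4.08, and Pnrc1, Dtx4 and Bnip3 by 3.74, 3.73 and 3.50. Zyx fell by 4.38 ± 0.70 (adjusted p = 0.000178), Cemip fell by 3.96 ± 0.44, the tropomyosin gene Tpm2 fell by 3.35 ± 0.42 and the actinin gene Actn1 fell by 3.22 ± 0.73. Bok, Aif1l, Ddah1 and Cks2 fell by 3.20, 3.17, 3.14 and 3.03. Dcn stood at 1.65 and no longer passed with the sign of all day 0 arrays turned, nor did Nrep, Bnip3, Actn1 and Cks2, while Clu, Dtx4 and Selenop passed at 4.82, 4.72 and 3.62. Zyx, Tpm2, Ddah1 and Cemip then stood at -2.92, -2.69, -2.63 and -2.32.

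**Figure D3:**
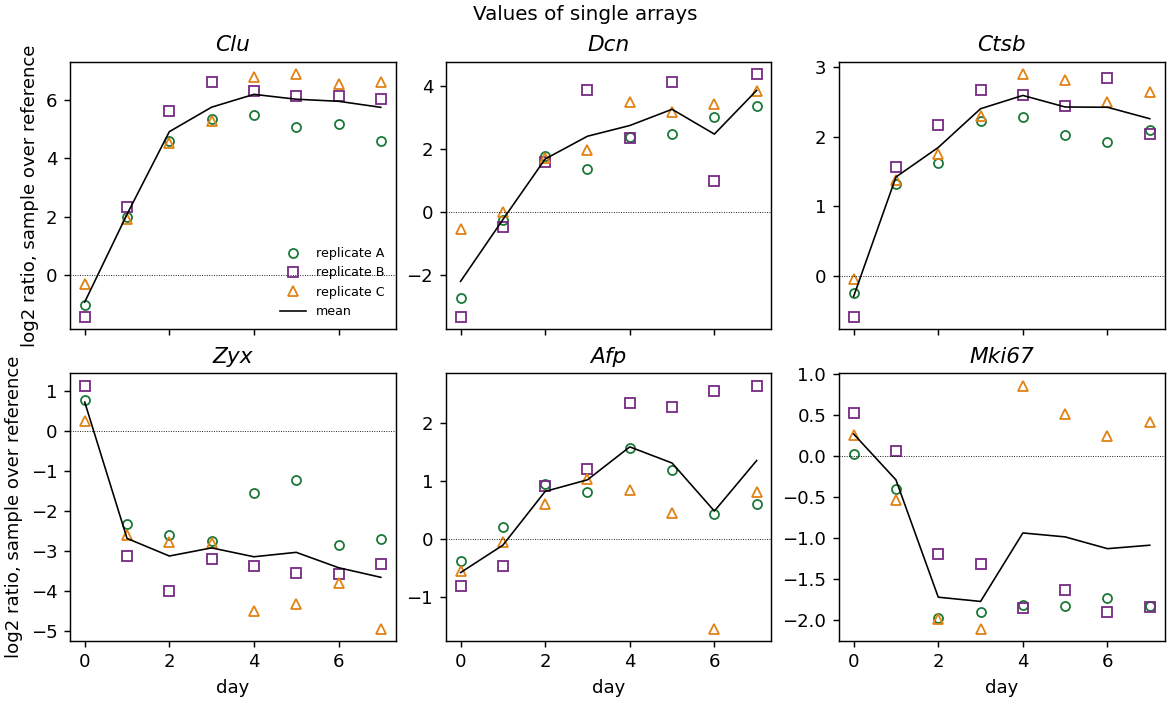
Log2 ratio of sample over reference for 6 genes on each of the 24 arrays against day, with symbols for replicate letters and a line through the day means. Clu rises from day 0 to a plateau on all letters, and Mki67 lies at 0.24 to 0.85 on the C arrays of days 4 to 7 but at -1.90 to -1.64 on the A and B arrays.

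Lysosomal transcripts were higher and cell cycle transcripts lower as sets at day 7. Of 22 lysosomal members 15 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 1.53 and an adjusted p of 1.47e-13, or adjusted p = 0.00443 with an estimated correlation. Ctsl, Lamp2, Ctsb and Hexa rose by 2.74, 2.60, 2.55 and 2.48. Of 39 transcripts of DNA replication and the cell cycle 24 fell and 0 rose (27 and 0 over the list alone), with a median of -1.15 and an adjusted p of 1.46e-11, or adjusted p = 3.86e-05 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, fell by 2.50 ± 0.56, Ube2c by 2.26 ± 0.34 and the thymidine kinase gene Tk1 by 2.19 ± 0.67. With the sign of all day 0 arrays turned, the medians of these lists were 1.08 and -1.10.

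Of 20 cytoskeletal transcripts 9 fell and 3 rose at day 7 (11 and 3 over the list alone; median -1.04, adjusted p = 0.00293, and adjusted p = 0.197 with an estimated correlation). Actb, the gene of beta-actin, fell by 2.82 ± 0.85, Tmsb4x, of an actin-binding peptide, by 2.52 ± 0.38, and the tubulin gene Tubb6 by 1.99. The C arrays carry part of this fall: without those of days 4 to 7 the call stayed, at a list median of -0.70, and Actb stood at -1.71, -0.98 and -4.04 on day 7 arrays A, B and C. Of 16 integrin and focal adhesion transcripts 8 fell and 2 rose (8 and 2 over the list alone; median -0.88, adjusted p = 0.0206, and adjusted p = 0.411 with an estimated correlation), among them Itga3 and Cav1, the gene of caveolin, by 2.82 and 2.25. Of 47 ribosomal protein transcripts 5 fell and 0 rose (1 and 0 over the list alone; median -0.42, adjusted p = 0.0219, and adjusted p = 0.55 with an estimated correlation). With the sign of all day 0 arrays turned, the cytoskeletal call stayed at a median of -1.04, and the integrin and ribosomal calls were lost, at -0.33 and -0.11. The integrin call was also lost with array C of day 0 turned (-0.64) or left out (-0.89), and the ribosomal call without day 0 array A (-0.36) or day 7 array A (-0.34).

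**Figure D4:**
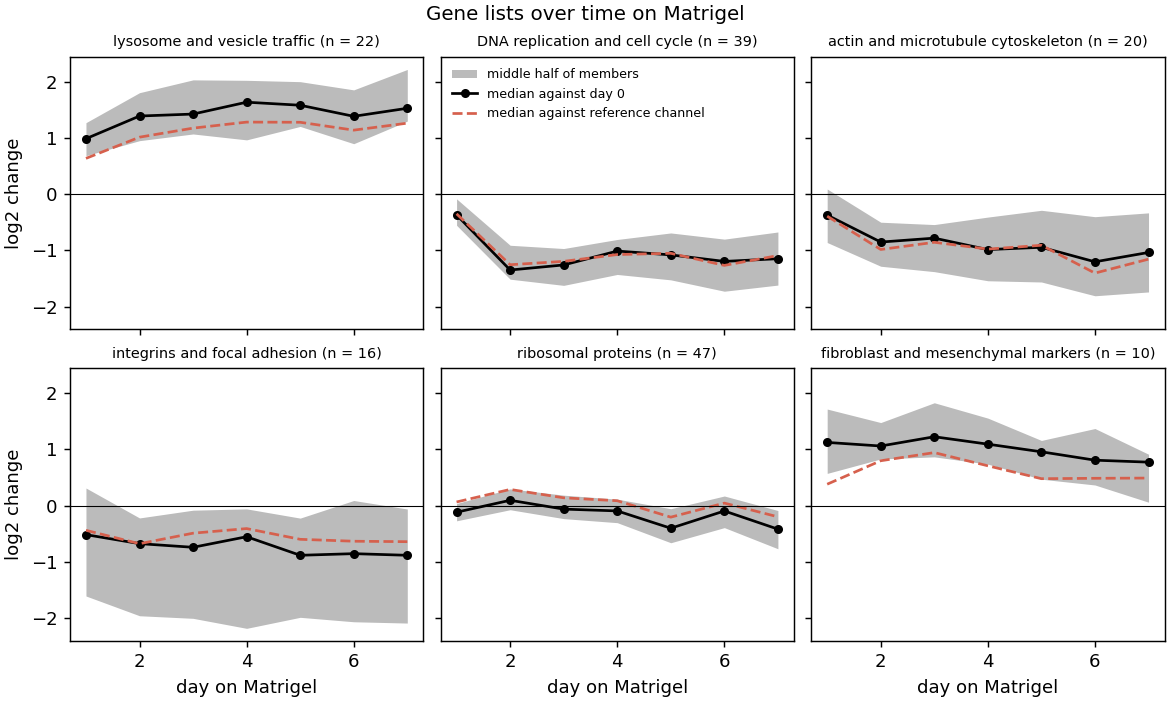
Median log2 change of 6 fixed gene lists against day 0 on each day on Matrigel (black line and points), the middle range of their members between the quartiles (grey), and the median against the reference channel (dashed). The lysosomal median lies between 0.99 and 1.64, and the cell cycle median falls from -0.37 at day 1 to -1.35 at day 2.

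The remaining lists did not pass as sets at day 7 by cameraPR, though fry called some of them, as given below. The hepatocyte, ductal and Notch lists were measured only in part (4 of 37, 4 of 26 and 11 of 34 fixed members). They are too sparse to judge hepatocyte or duct differentiation. Of 4 hepatocyte and hepatoblast markers measured, 3 rose and 0 fell (3 and 1 over the list alone, the latter Apob at -0.38; adjusted p = 0.354): H19 and Igf2, imprinted transcripts of fetal liver, by 3.34 ± 0.84 and 1.80 ± 0.59, and Afp, the serum protein of fetal liver, by 1.93 ± 0.69 (adjusted p = 0.0427). The calls of Afp and Igf2 were lost with all day 0 signs turned, and that of Afp with array C of day 0 turned. Afp also no longer passed without any 1 of the day 0 arrays, without day 7 array B (1.29) or without day 7 array C. It stood at 0.61, 2.65 and 0.81 on day 7 arrays A, B and C. On day 0 arrays A, B and C it stood at -0.37, -0.80 and -0.56, so leaving 1 of these out changed the size of its rise little. Of 4 ductal markers Anxa4 rose by 1.27 ± 0.21. Of 24 TGF-beta and BMP pathway transcripts 9 rose and 3 fell (12 and 3 over the list alone; adjusted p = 0.0655), with Tgfbi at 2.98 ± 0.55 and the antagonist gene Fst at -1.76 ± 0.30. Of 14 Wnt pathway transcripts 4 rose and 1 fell (4 and 1 over the list alone; adjusted p = 0.434), with Fzd1 at 3.37 and the beta-catenin gene Ctnnb1 at 1.89. Csnk1a1, at 0.79, had 1 of 5 features opposite in sign. Of 12 matrix proteases and inhibitors 5 rose and 1, Timp3, fell by 2.19 (5 and 1 over the list alone; adjusted p = 0.052). Of 11 Notch pathway transcripts Hes6 and Adam17 rose by 1.24 and 0.75, and of 14 junction transcripts 1 rose and 2 fell. Of 9 growth arrest transcripts 2 rose, Btg1 by 2.63 and Gas6 by 1.06, and 2 fell; their median was -0.17 and the test leaned upward (adjusted p = 0.977). Of 12 interferon response transcripts 2 rose and 4 fell, of 16 of glycolysis and hypoxia 3 rose and 1 fell, and of 33 of oxidative phosphorylation 3 rose and 4 fell. Of 14 detoxification transcripts 1 rose and 3 fell; the riser, Gstm1, had 1 of 2 features opposite in sign. Of 22 of the unfolded protein response 2 rose and 1 fell, of 12 of cholesterol and fatty acid synthesis 0 rose and 1 fell, and of 6 of inflammation Socs3 and Stat3 rose by 1.65 and 1.25. None of 10 extracellular matrix, 6 immediate early and 2 endothelial transcripts passed (0 each). Of 10 fibroblast markers 3 rose and 0 fell (4 and 0 over the list alone; median 0.77, adjusted p = 0.052): Dcn, Pdgfrb by 1.82 and Prrx1 by 0.95. Of 3 blood cell markers Tyrobp rose by 2.29, and of 2 smooth muscle markers Mylk rose by 2.10 and Smtn fell by 0.98. Bmp4, Id2 and Id3 stood at -0.94, -0.17 and 0.86 (adjusted p = 0.176, 0.853 and 0.0714). The value of Bmp4 rests on day 7 array B, at 0.71 against -1.42 and -2.49 on A and C, and without that array Bmp4 passed at -1.82.

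At day 7, 81 named genes passed the threshold. With the sign of all day 0 arrays turned, 35 stayed past it in the same direction, 45 no longer passed, Dcn among them, and 1 changed sign. Against the reference channel, with no day 0 array in the contrast, 81 of the 81 stayed. A dye bias is then not removed, and the day 0 arrays still enter the shared estimate of spread. The mean of a single day also has a smaller standard error than a difference, which makes staying past the threshold easier. The count of 2940 fell to 1874 without day 0 array A and 1616 without day 0 array B, and was 3355 without the C arrays of days 4 to 7.

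Many units called at day 1 were called again at day 7. In the same direction were 856 units, 416 higher and 440 lower, which is 73.7% of the day 1 calls, and 5 were called in opposite directions. With the sign of all day 0 arrays turned 279 units were called in the same direction, 54.2% of the day 1 calls, and with only array C turned 1282, or 75.2%. Independent lists of these sizes would share 77.5 higher and 82.2 lower units. In simulations of unchanged groups against the same day 0 arrays the highest count was 1. Unchanged groups give few calls on either day, so this count cannot show how far the shared arrays raise the overlap. The changes at days 1 and 7 correlated at 0.785 across units, against 0.498 in the simulations, with a covariance of 0.467 against 0.0738 and a difference of 0.393. Part of the excess may come from the shared day 0 arrays, which are too few to split. Against the reference channel, with no day 0 array in the contrasts, 1170 units were called in the same direction on both days and 20 in opposite directions. More units were called there, 1720 at day 1 and 3733 at day 7. The share was 68.0% of the day 1 calls, and the changes correlated at 0.66. Without the C arrays of days 4 to 7 the count against day 0 was 1589.

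Days 5 to 7 differed from days 1 to 3 in smaller changes. The day 0 arrays are not in this contrast and enter only the shared estimate of spread. Clca3a1 rose by 2.51 ± 0.26 (adjusted p = 6.52e-05, limma, 9 arrays per side), Ndufaf2 by 1.12 ± 0.17 and Myo10, an unconventional myosin gene, by 1.04 ± 0.14. Msmo1 and Insig2, genes of sterol synthesis and its control, rose by 0.93 ± 0.12 and 0.84 ± 0.11. Niban2 fell by 1.65 ± 0.30, the interferon-induced gene Ifitm1 by 1.61 ± 0.30, Zbp1 by 1.58 ± 0.35 and the syndecan gene Sdc1 by 1.28 ± 0.17. Plekhb2, Prmt9 and Smim6 rose by 0.99, 0.86 and 0.84, and Pbx3, Gpx1, Rbm46 and Rbm10 fell by 0.89, 0.87, 0.86 and 0.81. In all, 823 units passed (373 higher, 450 lower). The 9 arrays of a side are not independent, as given below. With the letter within a period as a random block, 5 of the 60 genes named for this comparison still passed.

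Between these periods 5 lists passed at the preset correlation and 0 with an estimated one. Of 47 ribosomal proteins 5 fell and 0 rose (5 and 0 over the list alone; adjusted p = 0.000683, and adjusted p = 0.402 with an estimated correlation). Of 22 lysosomal transcripts 3 rose, Hexa, Atp6ap1 and Ppt1, and 0 fell (8 and 0 over the list alone; adjusted p = 0.00124, and adjusted p = 0.402 with an estimated correlation), but the list median of 0.35 became -0.03 with arrays scaled. Of 39 cell cycle transcripts 3 fell and 0 rose (4 and 0 over the list alone; adjusted p = 0.0319, and adjusted p = 0.402 with an estimated correlation), and the median of -0.25 became 0.06 with arrays scaled. Of 20 cytoskeletal transcripts 3 fell, Tagln2, Tmsb4x and Tpm2 by 1.62, 1.54 and 1.08, and 0 rose (3 and 1 over the list alone; adjusted p = 0.045, and adjusted p = 0.47 with an estimated correlation). Of 12 cholesterol synthesis transcripts Msmo1, Idi1 and Stard4 rose by 0.93, 0.80 and 0.51 and 0 fell (5 and 1 over the list alone; adjusted p = 0.045, and adjusted p = 0.402 with an estimated correlation). Of 10 fibroblast markers Dcn rose by 1.91 ± 0.40, and Col5a2, Col6a2 and Col5a1 fell by 1.00, 0.96 and 0.85 (2 and 4 over the list alone; adjusted p = 0.217).

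Leaving out any of 12 single arrays ended the cytoskeletal call (medians -0.39 to -0.17), as did any of 12 for cholesterol synthesis (0.01 to 0.09) and any of 4 for the cell cycle, namely day 1 B, day 3 B, day 6 C and day 7 B (-0.25 to -0.18). For the cytoskeleton these were day 1 C, day 2 A and C, day 3 A, B and C, and arrays B and C of days 5, 6 and 7. For cholesterol synthesis they were arrays A and C of days 1, 2, 3 and 6, and arrays A and B of days 5 and 7.

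Arrays of a letter deviated together within each period, so the 9 arrays of a side are not independent. With the letter within a period as a random block, at an estimated correlation of 0.494, the count was 11, and 5 of the 60 named genes still passed: Clca3a1, Ndufaf2, Plekhb2, Sdc1 and Tagln2. The count was 407, 516 and 470 without day 1 array A, B and C, 486, 463 and 511 without day 2 array A, B and C, 403 and 444 without day 3 array A and C, 446 and 432 without array C of day 5 and of day 7, and 1249 without day 7 array B.

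With all arrays in the unblocked fit, steps between neighbouring days gave calls only from day 1 to day 2, where 64 units passed (22 higher, 42 lower), or 311 with the letter as a block within the period. Each later step then gave 0 calls by limma. Without day 6 array A, however, the step to day 6 gave 6 calls and the step to day 7 gave 47 (35 higher, 12 lower). Day 6 then rests on arrays B and C, and its array B deviated from its neighbours, as given below. Without day 6 array B, or without array C, both steps gave 0 calls. The count at these steps thus depended on which day 6 array was left out. Units at an unadjusted p under 0.05 numbered 79, 204, 44, 448 and 643 for the steps to days 3, 4, 5, 6 and 7, and 618 for the step to day 2. The count of 64 was 28, 14 and 30 without day 1 array A, B and C, and 6, 39 and 11 without day 2 array A, B and C. With the letter within a period as a fixed block, the step from day 3 to day 4, which crosses the periods, gave 8 calls. As a random block within a period, or as a block over all days, the letter left 0 calls at this step.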

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

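All tests of the C arrays, of the fibroblast markers and of a turned sign were chosen after the results were seen, while the test of transcripts translated at the endoplasmic reticulum was written down before its result.

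By limma's test of the difference itself, the effects at day 7 and at day 1 differed for 24 of the 112 genes named for either day. Of these, 12 were higher at day 7 and 12 lower. Over all 10639 units tested 311 passed, 171 of them genes. Most of the 112 were named for a large or called change in these same data. Such a choice favours a difference, so their share is not a separate result. Day 7 minus day 1 was 4.10 for Dcn (adjusted p = 0.00248), 3.67 for Clu (0.000713), 3.02 for Selenop, 2.42 for Dtx4, 2.18 for Mylk and 2.15 for Gas6. It was 1.49 for Ctsl, 1.39 for Idi1, 1.34 for Aldh1a1, 1.32 for Lamp2, 1.14 for Hexa and 1.13 for Msmo1. Aldh1a1 was called lower than day 0 on both days, Idi1 and Msmo1 at day 1 only (-0.61 and -0.30 at day 7, adjusted p = 0.222 and 0.308), and Gas6 stood at -1.09 and 1.06. Lower at day 7 were Tmsb4x (-2.09, adjusted p = 0.00502), Ndrg2 (-2.05), Bok (-1.79), Mt2 (-1.72), Itgb3 (-1.69), Col5a1 (-1.60), Fst (-1.59) and Tpm2 (-1.56). The others were Adamts4 (-1.39), Hba-a1 (-1.34), Itga6 (-1.17) and Cks1b (-1.02). Without the C arrays of days 4 to 7, the differences of Cks1b, Hba-a1, Tpm2 and Mt2 no longer passed (adjusted p = 0.168, 0.0739, 0.117 and 0.0967). With the letter within a period as a random block those of Ctsl, Cks1b, Hba-a1, Tpm2 and Mt2 did not (0.0811, 0.0624, 0.069, 0.0545 and 0.054).

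The C arrays of days 4 to 7 stood apart from the A and B arrays of their days. Spot or printing faults are argued against by features of the same gene, whose deviations correlated at 0.438 over 1637 feature pairs, and a wider scale alone by the correlation of the C mean with the A and B mean, 0.638 against 0.803 between A and B. A separate culture, RNA amplification or reference preparation may lie behind the C arrays: their deviation recurred between days with a mean correlation of 0.752. These cannot be told apart, since nothing in the labels says what a letter marks, and a difference in the cells is as open as one in the RNA. On these arrays Mki67, a proliferation marker, averaged 0.50 against -1.81 on the A and B arrays. The median of all cell cycle transcripts lay -0.23 from A and B, within the range of random lists (-0.36 to 0.25). Those of cytoskeletal and Notch pathway transcripts lay below their ranges, at -0.57 (-0.47 to 0.34) and -0.96 (-0.75 to 0.53). The other lists compared lay within theirs. Many lists were compared without adjustment, and random lists ignore correlation within a list, so single lists may lie outside by chance.

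The median of the fibroblast and mesenchymal list lay above day 0 on each day on Matrigel, at 0.77 to 1.22. Of its 10 measured members 3 to 7 were called higher and 0 lower. As a set the list passed at day 1 but not at day 7 (limma cameraPR adjusted p = 0.000377 and 0.052). With an estimated correlation it passed at neither (adjusted p = 0.138 and 0.55). Its day 1 call was lost with all day 0 signs turned, and days 2 to 6 were not tested as sets. Low values on the day 0 arrays alone are argued against on days 2 to 4 by the list median against the reference channel, 0.71 to 0.94, but stay open for days 1 and 5 to 7, where it was only 0.38 to 0.49. A growing share of feeder fibroblasts as the cause of the later rise of Dcn is argued against by the other 9 members: with letters as units their median changed by -0.25 (bounds at the threshold of 0.05, -0.57 to 0.07) from days 1 to 3 to days 5 to 7, and Dcn by 1.91 (1.21 to 2.62). More feeder fibroblasts by day 3 stay open: 10 of 10 members lay above day 0, although the feeder layer was stripped before culture per the labels. The abundant collagen transcripts Col1a2 and Col3a1 stood at 1.18 and 1.93 and Dcn at 4.60. On the day 0 arrays these genes averaged -0.49, -0.6 and -2.2, so part of each difference comes from the day 0 level. Dcn was at -2.72, -3.34 and -0.54 on day 0 arrays A, B and C. Against the reference channel it stood at 3.86 at day 7. Expression of the genes of this list by the hepatoblasts themselves was not tested and stays open too.

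Day 0 arrays A and B differed from day 0 array C in the same genes. Whether the sign of array C was turned cannot be decided from its correlations with B, 0.084, and with A, -0.343. Arrays A and B themselves correlated at only 0.755, so a turned array C need not mirror both alike. Lower recovery of transcripts translated at the endoplasmic reticulum on arrays A and B may account for part of it: a list of 40 such genes had a median difference of -0.43, at percentile 0.01 of random lists, and ribosomal proteins one of 0.52, at percentile 100. Day 6 array B deviated from its neighbours along a related axis (correlation 0.51 over 8210 units), but there the same list, at -0.31, lay at percentile 9.27, inside the random range, while ribosomal proteins lay at 0.63, percentile 100, as at day 0. The lysosomal and fibroblast lists also lay lower on day 0 arrays A and B than on C, at -0.653 and -0.905, percentiles 0 and 0.01 of random lists. Random lists ignore the correlation between genes of a list, so these percentiles only describe. The labels name no biological difference between day 0 arrays. A difference in the cells, such as in feeder fibroblasts, was not told apart from lower recovery.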

How the results depend on the processing

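Leaving out the C arrays of days 4 to 7, turned signs of day 0 arrays, and the letter within a period as a random or fixed block were chosen after seeing the data, and all other alternatives before. Named genes kept their direction and side of the threshold in 2191 of 2443 recomputed values under alternatives other than leaving out arrays, lost the call in 235, gained it in 9 and changed sign in 8. Signal over background is not used here, so what it limits is unknown. Where no cause is given, the cause was not tested.

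With arrays scaled to a common deviation the counts were 3259 at day 1, 3620 at day 2, 2655 for the whole course and 165 for the steps, and with quantile normalization 3127 and 3484 at days 1 and 2. Quantile normalization called 11, 8 and 3 lists for day 1, day 7 and late against early days, in place of 7, 5 and 5. Units with a value on all arrays gave 592, 1200 and 1651 at days 1 to 3, from fewer units tested, with 11 lists at day 1 and 3 for late against early. No filter gave 1836 at day 1 and 8 lists at day 7. A fit on the compared groups only, with fewer arrays, gave 2577, 3330, 1212, 1117, 1449 and 1607 at days 1, 2, 4, 5, 6 and 7, and 465 for the steps. Day 2 against the reference channel gave 2740. A minimum change of 1 (log2) left, by its construction, 1200, 1706 and 1955 at days 2, 3 and 7 and 134 for late against early.

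Without the C arrays of days 4 to 7 the counts were 2271, 3312 and 3941 at days 1 to 3, 3166 for the whole course, 178 for the steps and 1589 for the overlap of day 1 and day 7, with 11 lists at day 1 and 3 for late against early. With all day 0 signs turned they were 515, 1109, 1366, 1499, 1342 and 1230 at days 1, 2, 3, 4, 5 and 7, 1085 for the whole course and 279 for the overlap, with 3 lists at day 7. Turning the sign of day 0 array C alone moved no count by over 1.5 times. With an estimated correlation between genes 2, 2 and 0 lists were called for day 1, day 7 and late against early. The test fry, which asks another question, called 14 at day 1 and 11 at day 7, some of them not passing by cameraPR. Of the latter, upward at day 7 were TGF-beta and BMP, Wnt, matrix proteases, hepatocyte markers, glycolysis and inflammation (fry adjusted p = 0.00118 to 0.033). Upward at day 1 were TGF-beta and BMP, Wnt, inflammation and blood cell markers (fry adjusted p = 0.0069 to 0.0191). Downward at day 1 were integrins, growth arrest and smooth muscle (fry adjusted p = 0.00405 to 0.038).

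The replicate letter as a block over all days, where letters are not known to pair between periods, gave 1543 for late against early, 115 for the steps and 3 lists for late against early, and moved no other count by over 1.5 times. Of 24 arrays, 18 correlated best in their deviations with their own letter. The letter within a period as a random block gave 11 for late against early and 345 for the steps, and as a fixed block 311 for steps within a period. The random block sets periods against the spread between letters, of which each period has 3.

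Sign changes were these. With arrays scaled, late against early, the medians of cell cycle and lysosomal transcripts became 0.064 and -0.032, Timp3 became 0 and Bnip3l -0.018. With quantile normalization the test of the cell cycle list turned, at a median of -0.054. With all day 0 signs turned, Csnk1a1 was -0.072 at day 1 and -0.017 at day 7, Cks2 0.26 and Afp -0.68 at day 1. Against the reference channel Afp was -0.10 at day 1. Id2 at day 7 was 0.27 without the C arrays of days 4 to 7 or without the C array of day 7, 0.086 without letter C and -0.54 without the B array of day 7, against -0.17 in the fit of all arrays.

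Leaving out single arrays or all arrays of a letter gave 57 to 1565 units at day 1, 333 to 2328 at day 2, 502 to 3149 at day 3, 795 to 2585 at day 4, 890 to 2624 at day 5, 1200 to 2865 at day 6 and 1019 to 3100 at day 7. It gave 55 to 1249 for late against early, 236 to 2086 for the whole course and 1 to 112 for all steps together. Lists called were 6 to 10 at day 1, 4 to 7 at day 7 and 2 to 5 for late against early. The lowest counts at days 1 to 4 and 7, for the whole course, late against early and the steps came without letter A.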

Other observations

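The lists of FOXO and YAP/TAZ target genes were chosen after the changes that prompted them were seen, but the predictions were written before the tests, and members whose values had been looked at were left out. Tgfb2 and Klf6 stayed in, although they belong to fixed lists whose results had been seen; without them, tested after the results, the p at day 7 was 0.313 for YAP/TAZ (n = 12 genes) and 2.75e-06 for FOXO (n = 10 genes).

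The FOXO list holds some genes of autophagy, by which cells deliver their own material to lysosomes, and no list of autophagy genes was tested. At day 7 Map1lc3b, whose protein coats autophagosomes, rose by 2.25 ± 0.31 (adjusted p = 4.15e-05, limma, n = 3 arrays per day), the cargo receptor gene Nbr1 by 1.77 ± 0.29, Pink1 by 1.55 ± 0.27, the kinase gene Ulk1 by 1.20 ± 0.20 and Atg14 by 1.00 ± 0.19. Atg12, at 0.77 ± 0.32, did not pass (adjusted p = 0.0776). These genes were chosen as members of the FOXO list, outside the rule for named genes.

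Single rises at day 7, such as those of Btg1 and Bnip3 (2.63 and 3.50), prompted a test of FOXO target genes, and higher activity of FOXO transcription factors is a candidate explanation. The fixed list of growth arrest did not rise as a set (2 higher, 2 lower, median -0.17, limma adjusted p = 0.977). The 11 members not looked at before were higher as a set at day 7 (limma cameraPR p = 1.09e-05, n = 11 genes, median 1.00), and 7 rose and 0 fell, among them Tsc22d3 by 1.27 and Fbxo32 by 0.66. The p stayed between 1.89e-06 and 0.000326 over 22 alternatives. At day 1 it was 0.00214, with 4 higher and 0 lower, and it missed the threshold in 1 of 22 alternatives, all day 0 signs turned (0.103). The 5 autophagy genes above supply most of the rises and are also targets of other regulators, so the test does not single out FOXO.

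The cytoskeletal and integrin lists were lower at day 7 at the preset correlation but not at an estimated one (limma adjusted p = 0.197 and 0.411), and the integrin call was lost with all day 0 signs turned. Lower activity of YAP and TAZ may be involved. The 13 members of a target list not looked at before had a median of -0.30 at day 7 (limma cameraPR p = 0.353, n = 13 genes), and over 22 alternatives the p was 0.191 to 0.777, so the prediction for day 7 was not met. The bound written beforehand counted any p at or above the threshold as evidence against a fall, which was wrong, since such a p excludes no fall of this size, and the verdict was changed to undecided after the result was seen. At day 1, for which no prediction was written, the p was 0.0243, or 0.0486 at an estimated correlation, and it missed the threshold in 3 of 22 alternatives (0.00514 to 0.0682), with Tead1 at -1.36 and Lats2 at -1.56.

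The rise of Hba-a1 at day 1 rests on arrays A and C (2.10 and 1.89), while array B stood at 0.02. Fam110c, chosen after its values were seen, was called lower at day 1 (-0.86) and higher at day 7 (0.75).

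Other splits of the arrays were counted for each comparison. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. Against day 0 the real split was the 1 split with the most calls on each day: 1161, 1818, 2599, 2359, 2435, 2642 and 2940 for days 1 to 7, where the highest other split gave 0, 4, 3, 10, 1, 863 and 3. The 863 came from setting day 0 A and B with day 6 B against the rest, which points to a structure of these arrays. For the step from day 1 to day 2 the real split gave 64 and the highest other 0. The later steps gave 0 calls, so all 10 splits gave as many, and the highest others were 1, 0, 63, 809 and 459. Within a period the letters pair the arrays, and among the 4 splits that part as many pairs as the real one the highest other gave 0 for every such step. The splits with 63, 809 and 459 calls part fewer pairs and leave both C arrays on one side, which points to the C arrays as a structure.

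For any change over days 0 to 7, only the real grouping among 100 gave as many calls (1738, highest other 2). For days 5 to 7 against days 1 to 3 it was likewise (823, highest other 4). Regrouping moves the differences between days and between letters into the error, so few calls were likely there. It therefore cannot exclude the letters as a source of the calls. Such regrouping takes single arrays as independent, which the shared deviations of letters contradict, and for late against early the random block, at 11 calls, is the stricter value.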
